A study of Mus musculus with 6 samples.

How the data were processed

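The libraries were made by TOP-seq (tethered oligonucleotide-primed sequencing), an assay in which an oligonucleotide is clicked onto azide groups on DNA and primes synthesis from the labelled position, so that each read starts near the CpG that carried the label. Mouse E14TG2a embryonic stem cells, an established pluripotent line, were grown for 48 h and then fed 2 mM of the azide-bearing methionine cycle analog S-(6-azidohex-2-ynyl)-L-homocysteine for 24 h in the presence of 200 µM methionine. Sonicated DNA (900 ng) entered each library, and the libraries were sequenced on the Ion Proton, per the labels' protocols. There were 3 libraries of cells with wild-type Dnmt1 and Mat2a and 3 libraries of cells that carry engineered versions of both genes, called double knock-in here. The labels number the replicates but do not say whether they came from separate cultures. The spread between these libraries, on which the p-values rest, may therefore be technical. P-values of moderated tests also draw on the spread of other features.

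The deposited files hold whole-number tag counts per CpG site, with zeros listed, and no scaling to library size. FastQC, cutadapt 3.4, BWA 0.7.17, SAMtools 1.9, R 4.3.0 and the mm10 build are named, per the submitters' processing notes. The order of these steps, any mapping-quality filter and any removal of duplicate reads are not given in the sources used here. All 6 files listed the same 21867837 CpG sites. Molecular identifiers are not mentioned, and amplified copies of 1 molecule would count as several tags, so intervals cover counting error only. Where sequence is present in near-identical copies, the tags of a gene depend on how such reads were treated, which is not stated.

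Tags were analysed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, R 4.3.3 and limma 3.58.1. Relative tag density is the tags per CpG site of a class or gene divided by the tags per CpG site of the same library over chromosomes 1 to 19 and X. A value of 1 is therefore the mean of that library, and relative density compares shares of tags and not amounts. Local CpG density was the number of listed CpG sites within 250 bp on either side, the site itself included. Tags expected for a gene were summed over its sites from the mean of sites of the same local density, multiplied by a factor for its chromosome, separately in each library. Values are given as mean ± SD over 3 libraries. Groups were compared with two-sided exact permutation tests, which cannot go below p = 0.10 with 3 against 3.

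Gene coordinates came from the RefSeq table of GRCm38.p6, the assembly behind mm10, which gave the start and end of each gene without strand or exons. The planned classes of transcription start sites, untranslated regions, exons and introns were therefore replaced. For each protein-coding gene, the end of the gene interval with more CpG sites within 500 bp, called the CpG-richer gene end, stood in for the promoter, and for some genes it is the wrong end. A gene body was the gene interval without 1000 bp at each end. Of 21627 protein-coding genes, 10677 had at least 40 CpG sites around the richer end (CpG-rich ends) and 7405 had at most 19 (CpG-poor ends).

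The share of tags in 100 kb windows, gene bodies and gene ends with at least 10 tags over the 6 libraries was compared between groups with a quasi-Poisson test with library sizes as offsets. Its dispersion was moderated across features with limma, and p-values were adjusted by the Benjamini-Hochberg method. This test replaced the quasi-likelihood and negative binomial tests fixed before the data were examined, which were not run. The reason was formal: the tables are tab-separated under a comma-separated name, their unit was therefore recorded as other although the values are whole-number tag counts, and packages for count models were then not used. Trimmed-mean scaling was not run for the same reason. In simulated data with the real depths the quasi-Poisson test called 0% of 50 features changed 4-fold upwards in windows, gene bodies or gene ends. It recovered 6% of 50 gene bodies raised 16-fold, and 68% of 50 windows of 1 Mb raised 16-fold. It called none of the unchanged features. At the depth of the wild-type libraries, a count of 0 therefore says nothing about the absence of a difference in share. Fold changes in share added 0.5 wild-type tags, as the same share, to both groups.

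A second test was chosen after seeing the data. It compared the tags of each gene body or gene end in the 3 double knock-in libraries with the tags expected from local CpG density and chromosome, again by a moderated quasi-Poisson test with Benjamini-Hochberg adjustment, for genes with at least 30 expected tags. It compares genes with one another within the double knock-in libraries and not the groups. A gene without a tag has no spread of its own, and its dispersion was taken from the trend over other genes. For the remaining genes the dispersion was drawn towards that trend, so a small p-value can stand beside a wide SD. In simulated data it recovered 92% of gene bodies raised 4-fold, 58% raised 2-fold and 38% lowered to 0.5 of the expected level, and called 0.0447% of 17909 unchanged bodies. For gene ends it recovered 38% raised 4-fold, 0% raised 2-fold and none of those lowered, and called 0.106% of 9458 unchanged ends. Unchanged features were drawn at exactly their expected tags. Variation by region or in mappability was not simulated, so these rates do not cover it, and a call need not be specific to the gene.

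The 12 gene lists were fixed before the data were examined. Each list was described by its relative density, its members' median, and the percentile of that median among 10000 random lists matched on the number of CpG sites (gene ends) or on CpG sites per kb (gene bodies), a comparison added after seeing the data. A percentile near 50 with a random median of 0 only shows that list and random genes lie at the floor. Lists were also tested with limma's cameraPR at a preset correlation of 0.01. Named genes were set by a rule fixed before the data were examined. It took the 10 genes of largest change in each direction past the share test, of which there were none. It further took the 5 gene bodies of highest and of lowest density with at least 50 CpG sites (ties at 0 resolved by the number of sites), Dnmt1 and Mat2a, and the members of each list with the largest and smallest fold change in share. Among members without a wild-type tag this ranks double knock-in tags and not a change. Results of some genes taken by the rule or counted in the lists are left out of the text because their names are withheld. Other genes are named as chosen after their values were seen. Alternatives left out the 0.01% of sites with the most tags, each library in turn and the chromosome term, counted each site as 1 or 0, and changed windows, filters and scaling. Mitochondrial and Y sites were kept out of the reference mean.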

Results

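The series measured, at CpG resolution, where an engineered DNA methyltransferase cascade labels the genome of living mouse embryonic stem cells. In the double knock-in cells, engineered Mat2a, a methionine adenosyltransferase, turns the fed analog into an extended cofactor, and engineered Dnmt1, the maintenance DNA methyltransferase, transfers the azide group to CpG sites. Wild-type cells fed the same analog were the control and show the background. Each group had 3 libraries. The wild-type libraries held 14134, 18178 and 19087 tags, and the double knock-in libraries 21391175, 20133191 and 19832760 tags over the same 21867837 CpG sites.

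Many more tags were recovered from the double knock-in cells than from the wild type. Totals were not set against the reads sequenced per library, so they compare tags and not amounts of label. The mean total was 20452375 ± 826800 tags (SD, n = 3) against 17133 ± 2637 in the wild type, 1194-fold more, and every double knock-in library lay above every wild-type library (two-sided exact permutation test, p = 0.10, the smallest that 3 against 3 allows). A tag was found at 6.57% ± 1.04 of the listed CpG sites in the double knock-in and at 0.0146% ± 0.00336 in the wild type (exact permutation p = 0.10). The single double knock-in libraries covered 6.56%, 7.61% and 5.53% of sites, and together they covered 3698101 sites. Each covered site held 14.5 ± 2.19 tags in the double knock-in and 5.45 ± 0.508 in the wild type, so repeated tags at a site were frequent in both groups. With every library thinned to 14134 tags, the double knock-in libraries covered 13962 to 14019 sites and the wild-type libraries 2450 to 3596, a ratio of 4.64 in place of 451, where thinning removes repeated tags from the double knock-in and leaves most of those in the wild type.

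**Figure D1:**
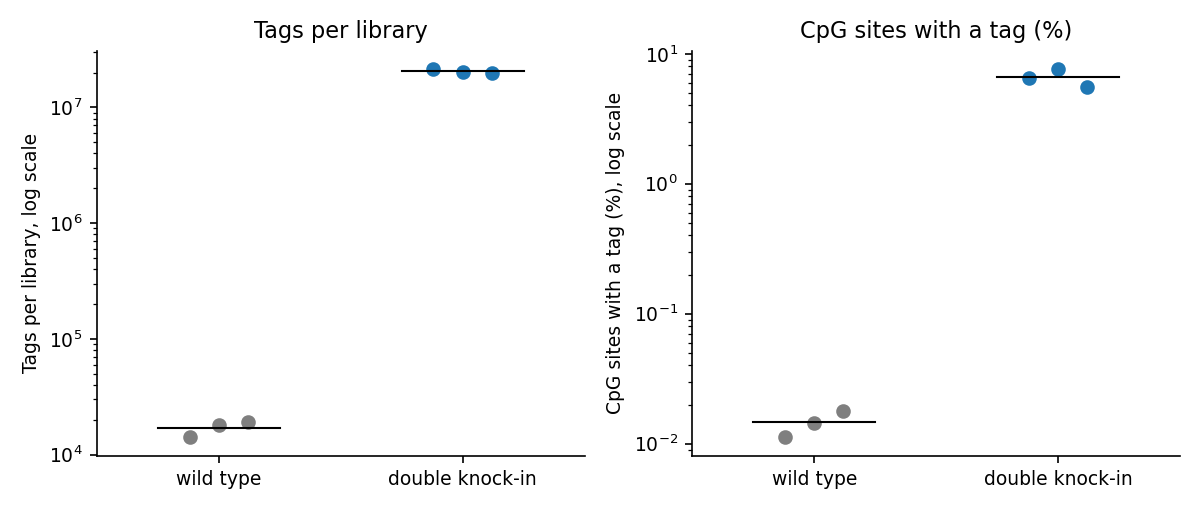
Tags per library (left) and percent of listed CpG sites with a tag (right), both on log axes. Points are the 3 libraries of each group and lines their means, which differ 1194-fold in tags.

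The double knock-in libraries were correlated with one another along the genome. Across 25702 windows of 100 kb, Pearson's r between double knock-in libraries was 0.904 to 0.924, between wild-type libraries 0.0144 to 0.0264, and between groups 0.0554 to 0.0930. Windows are not independent replicates, and these coefficients describe agreement only. The wild-type libraries held under 1 tag per window on average, so their coefficients do not show whether they share a landscape. In the double knock-in libraries the window at the 5th percentile had a relative tag density of 0.150 and that at the 95th percentile 1.96. Pairs of double knock-in libraries had 183868 to 257196 sites in common, 2.32 to 2.35 times the number expected of independent draws. Pairs of wild-type libraries had 11, 11 and 35 sites in common, 30.91, 25.04 and 61.46 times the expected number.

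The most CpG-dense sequence was nearly free of tags in the double knock-in cells, and tag density was highest at intermediate CpG density. CpG islands were not annotated. Sites with over 40 CpGs within 250 bp had a relative tag density of 0.00435 ± 0.00212 (SD, n = 3) in the double knock-in and 0.450 ± 0.0311 in the wild type. Sites with 21 to 40 CpGs nearby stood at 0.164 ± 0.0209 and 0.746 ± 0.0314. The highest density in the double knock-in was found at sites with 6 to 10 CpGs nearby, 1.35 ± 0.00737, against 1.14 ± 0.0526 in the wild type. Sites with 1 to 5 CpGs nearby stood at 0.839 ± 0.00915 and 0.906 ± 0.0256. All 4 of these differences separated every library of both groups (exact permutation p = 0.10 each, the smallest possible). Sites with 11 to 20 CpGs nearby overlapped between groups, at 1.22 ± 0.0318 and 1.18 ± 0.0386 (exact permutation p = 0.30). With CpGs counted within 100 bp, the ratios of the groups at sites with 1 to 5 and with 11 to 20 CpGs nearby turned to the other direction, at 1.04 and 0.306, because the same class then holds other sites.

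**Figure D2:**
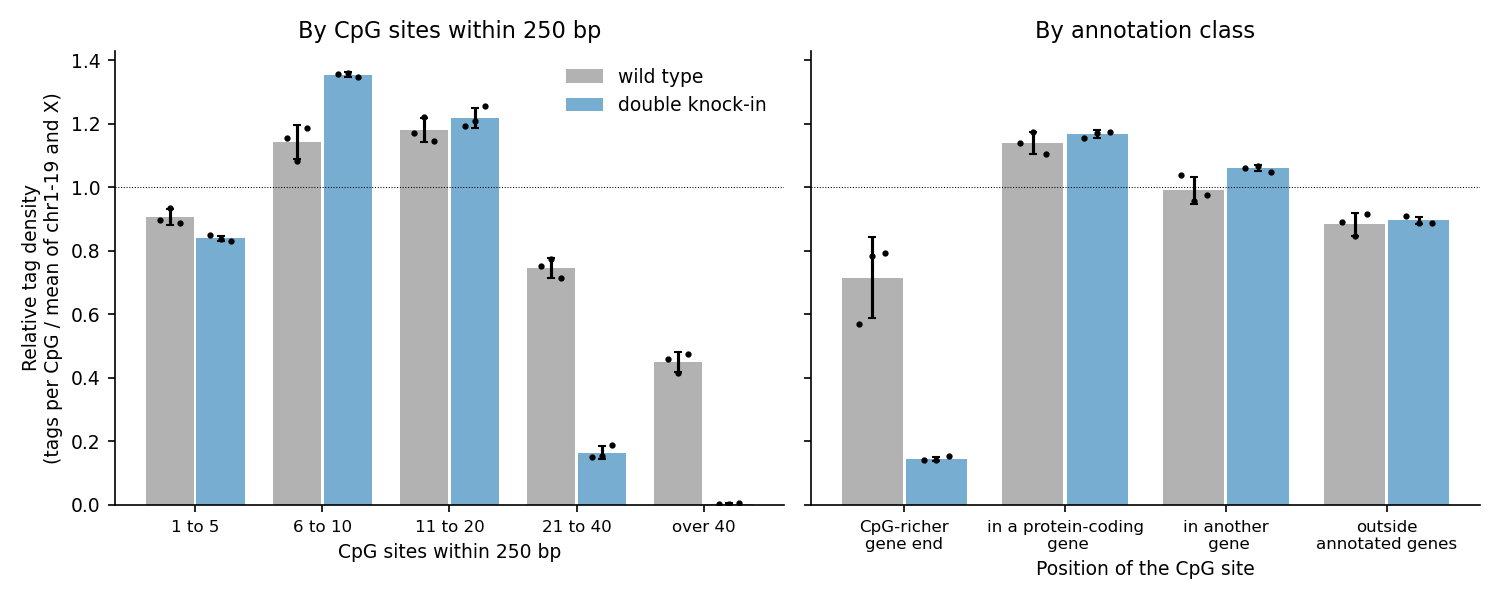
Relative tag density (1 is the mean of chromosomes 1 to 19 and X) by the number of CpG sites within 250 bp (left) and by position relative to genes (right). Bars are means of 3 libraries, error bars SD and dots single libraries. Sites with over 40 CpGs nearby stood at 0.00435 in the double knock-in and 0.450 in the wild type.

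The CpG-richer ends of protein-coding genes were sparsely tagged in the double knock-in. Their relative density was 0.145 ± 0.00678 (SD, n = 3) against 0.715 ± 0.126 in the wild type (exact permutation p = 0.10). CpGs inside protein-coding genes stood at 1.17 ± 0.0117 in the double knock-in and 1.14 ± 0.0359 in the wild type, a difference within the spread (exact permutation p = 0.40). CpGs outside annotated genes stood at 0.895 ± 0.0124 and 0.884 ± 0.0358 (exact permutation p = 0.90), and those inside other genes at 1.06 ± 0.00933 and 0.990 ± 0.0419 (exact permutation p = 0.10). Genes exceeded intergenic sequence at similar CpG density in both groups. Among sites with 6 to 10 CpGs nearby, the double knock-in density was 1.45 ± 0.0118 inside protein-coding genes and 1.24 ± 0.0159 outside annotated genes, and the wild-type density 1.25 ± 0.0191 and 1.01 ± 0.111.

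The depletion was sharpest at CpG-rich gene ends and was not seen at CpG-poor ones. Around the 10677 CpG-rich ends, the tag density within 200 bp was 0.0118 ± 0.00397 of that 2000 to 5000 bp away in the double knock-in (SD, n = 3), and 0.625 ± 0.227 of it in the wild type (exact permutation p = 0.10). Around the 7405 CpG-poor ends the same ratio was 1.10 ± 0.0311 in the double knock-in and 1.01 ± 0.599 in the wild type (exact permutation p = 1). Without wild-type replicate 2 or 3 the order of the groups at CpG-poor ends turned, at 0.893 and 0.971. At CpG-rich ends the depletion reached into the gene past the 1000 bp trimmed from bodies. The double knock-in relative density was 0.09575 at 1000 bp, 0.456 at 2000 bp and 0.689 at 3000 bp into the gene. Neither the expected tags nor the matching on CpG sites per kb accounts for distance to the end. Low values of short bodies may therefore include this depletion.

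**Figure D3:**
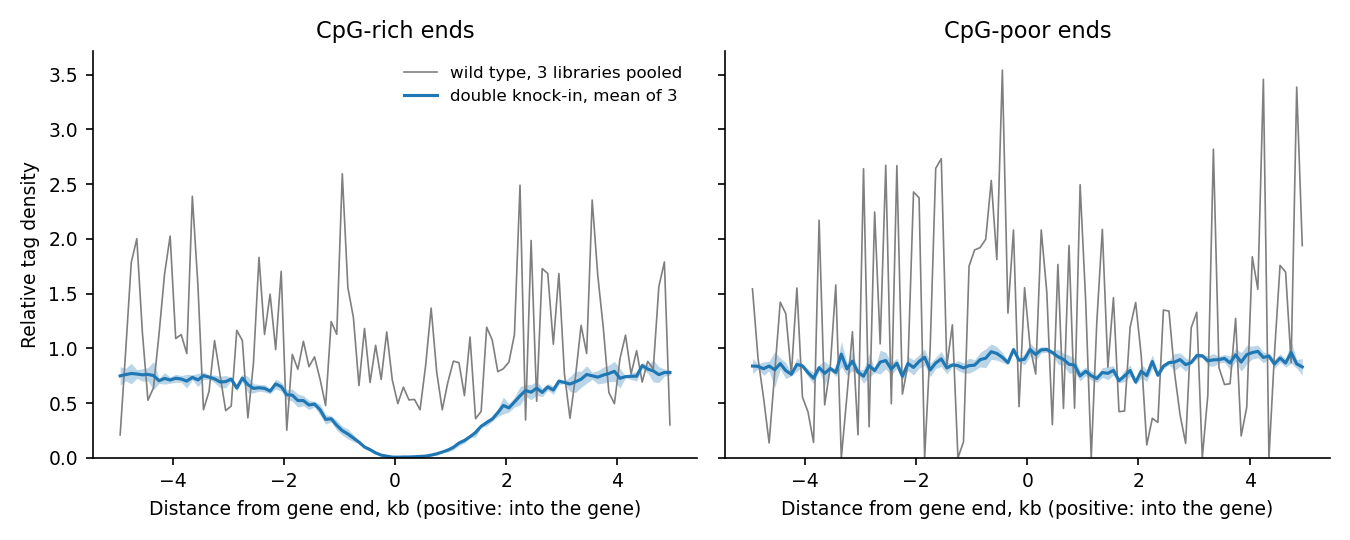
Relative tag density in 100 bp steps around the CpG-richer gene end, for CpG-rich and CpG-poor ends; positive distances, in kb, run into the gene. The blue line is the double knock-in mean with SD as a band (n = 3), and the grey line pools the 3 wild-type libraries. At CpG-rich ends the double knock-in ratio of centre to flank was 0.0118.

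Gene ends of the germline list stood out against other CpG-dense gene ends. Germline genes encode proteins of meiosis and of transposon silencing, and many have CpG-dense promoters. Their 26 gene ends had a relative density of 1.01 ± 0.224 in the double knock-in (SD, n = 3), only 2 members were at 0, and the members' median of 0.472 lay at percentile 100 of 10000 random lists matched on CpG number. The list held 2.97 ± 0.522 times the tags expected from local CpG density and chromosome. In the test against this expectation, 5 of 17 tested members passed as higher (Slc25a31, Tuba3a, Tex101, Dpep3 and Tdrd9) and none as lower. Adjusted over the list alone, 7 were higher and 2, Spo11 and Stag3, were lower. Of those above expectation, chosen after their values were seen, Tdrd9, a piRNA pathway helicase, stood at 10.9 ± 7.59 times the expected tags (adjusted p = 7.957e-15, limma-moderated quasi-Poisson), Tuba3a, a testis tubulin, at 6.35 ± 2.31 times (adjusted p = 5.904e-09) and Dpep3, a testis dipeptidase, at 6.43 ± 4.54 times (adjusted p = 2.049e-07). In bodies of the list, 4 of 25 were above and 2 below expectation (Syce1, Tdrd9, Mov10l1 and Tdrd1, and Sycp3 and Smc1b), at a relative density of 1.14 ± 0.0666. The Dazl end, of an RNA-binding protein of germ cells, also chosen after its values were seen, had 70 CpG sites and a relative density of 1.32 ± 0.461. The rule for named genes took Tuba3a, at a relative density of 3.92 ± 1.25, and Mov10l1, another piRNA pathway helicase, at 0.956 ± 0.851. The 3 wild-type libraries held 1 tag over all germline ends.

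Bodies of genes of the pluripotency network lay below the genome mean, with a low tag density in the typical member. They had a relative density of 0.541 ± 0.0491, and the members' median of 0.167 lay at percentile 0.02 of matched random lists. Divided by expectation they stood at 0.551 ± 0.0497. Neither comparison accounts for distance to the gene end, so part of this may be the depletion around CpG-rich ends. Against local expectation, 13 of 20 tested members were lower and none higher (15 lower over the list alone). Bodies of Pou5f1, which encodes Oct4, and of Klf4, chosen after their values were seen, had no tag in any double knock-in library. Their p-values rest on the spread of other genes (adjusted p = 0.0007686 and 0.004258, limma-moderated quasi-Poisson). Nanog, chosen in the same way, stood at 0.133 ± 0.167 of expectation (adjusted p = 0.001088). The rule took Jarid2, a Polycomb cofactor, at a relative density of 0.380 ± 0.0855 and Fgf4, a growth factor of the early embryo, at 0.153 ± 0.265. At pluripotency gene ends, 17 of 25 members were at 0 (64.2% of all 21516 gene ends were, and the list lay at percentile 49.35 of matched lists). Of 13 tested ends, 8 were lower over the list alone and none over all genes. Over all genes, 4262 of 9658 tested ends had an unadjusted p under 0.05 (limma-moderated quasi-Poisson). Counts of ends over a list alone, here or in other lists, therefore do not by themselves set a list apart. The rule took Esrrb, an orphan nuclear receptor, at a relative density of 2.23 ± 1.36.

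Bodies of housekeeping genes lay below the genome mean. They stood at 0.591 ± 0.0461, with 9 of 27 members at 0 and a median at percentile 0 of matched lists, and at 0.615 ± 0.0473 divided by expectation. As for the pluripotency bodies, part of this may be the depletion around CpG-rich ends. Against expectation, 12 of 24 were lower (13 over the list alone) and 1, B2m, was higher, chosen after its values were seen, at 2.24 ± 1.21 times (adjusted p = 0.03716, limma-moderated quasi-Poisson). Bodies of Gapdh (glycolysis) and Actb (cytoskeletal actin), chosen after their values were seen, had no tag (adjusted p = 0.0002161 and 0.01264, likewise from the spread of other genes). Both have processed copies elsewhere in the genome, so part of their tags may depend on the unstated treatment of shared reads. The rule took Rab7, a late endosome GTPase, at a relative density of 1.12 ± 0.296 and Gusb, a lysosomal enzyme, at 0.635 ± 0.236. At gene ends 24 of 27 members were at 0, at percentile 50 of matched lists, and the list had 0.00612 ± 0.00640 of the mean tag density. The wild type held 18 tags at housekeeping ends, all in replicate 2 and at Psmb4.

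Genes of differentiated tissues lay at the other side. Bodies of the tissue-specific list had a relative density of 1.46 ± 0.0261 and a median at percentile 99.7 of matched lists. Their gene ends stood at 1.30 ± 0.300, with a median at percentile 96.1. Against local expectation, 4 of 27 bodies were higher, among them Opn1sw, Cpa1 and Myh6, and 3 lower (Lck, Myl2 and Cela1). Over all genes, 2887 of 18109 bodies were higher and 4193 lower, so the share of higher bodies in the list was not raised. Of 23 tested ends, 1, that of Krt5, was higher. Opn1sw and Cpa1 lie on chromosome 6, which carried more tags as a whole; divided by expectation, which includes the chromosome, the list stood at 1.23 ± 0.0175 in bodies and 1.20 ± 0.289 at ends. The rule took Csn3, a milk casein, at 0.660 ± 1.02. The tissue-specific list held no wild-type tag in bodies or ends, so the rule ranked its members by double knock-in tags only.

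Bodies of developmental regulators marked by Polycomb, such as Hox and Pax genes, stood at 0.581 ± 0.00819 with a median of 0.104 at percentile 4.46 of matched lists. Divided by expectation they stood at 0.821 ± 0.00928, with the median at percentile 5.775. Their ends stood at 0.0663 ± 0.0398 with 20 of 30 members at 0, at percentile 49.99 of matched lists and thus at the ordinary level of such ends. Of 24 tested bodies, 11 were below expectation and none above (12 and none over the list alone). The rule took Gata6, an endoderm regulator, at 0.872 ± 0.176, and Cdx2, a trophoblast and gut regulator, with no double knock-in tag. In the comparison of shares between groups, the bodies of this list were the only list below the 0.05 threshold, ranked lower than other genes (cameraPR, adjusted p = 0.00989, and adjusted p = 0.00379 with an estimated correlation). The median z of its members was 0.0689, so the rank does not show a lower share of the typical member. As relative density the wild-type libraries differed among themselves, at 4.59, 2.75 and 0.392 against 0.573 to 0.589 in the double knock-in (exact permutation p = 0.40). That call was lost without wild-type replicate 2, which alone held the 12 wild-type tags in Cdx2.

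**Figure D4:**
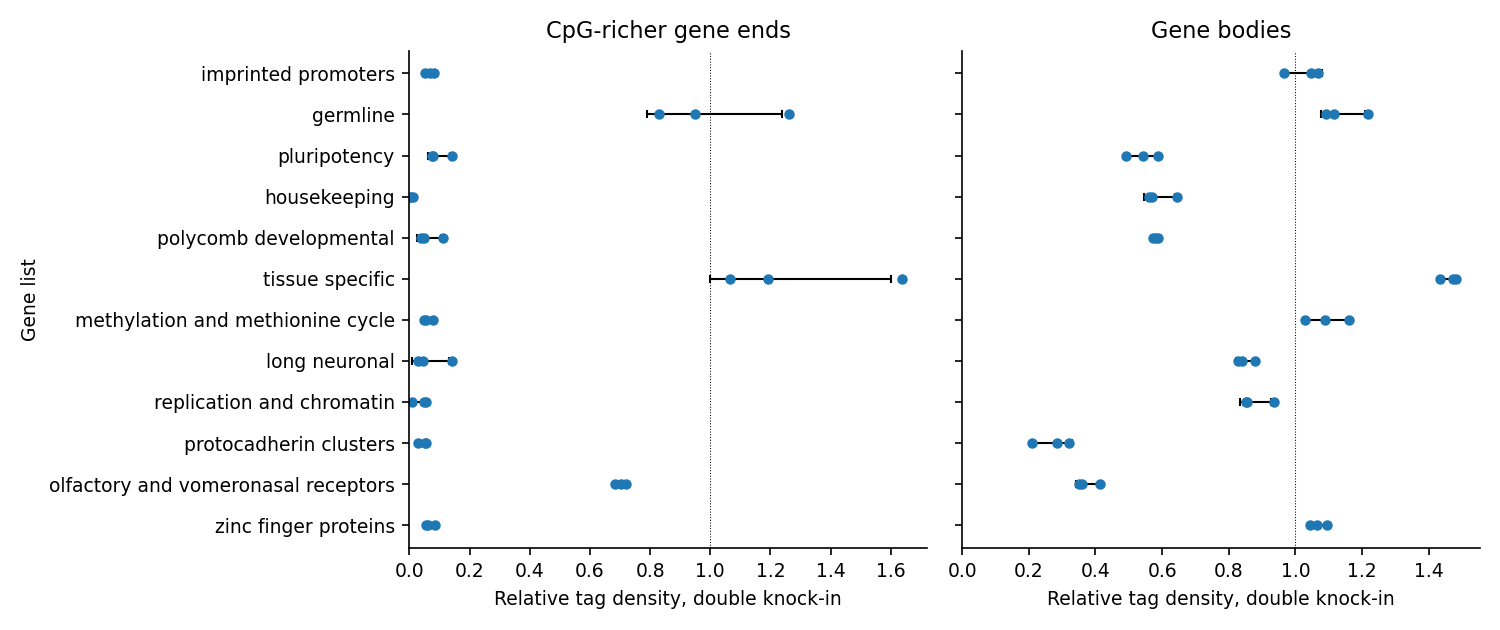
Relative tag density of the 12 gene lists in the 3 double knock-in libraries at CpG-richer gene ends (left) and gene bodies (right). Points are libraries and error bars SD around their mean. Germline ends stood at 1.01 and housekeeping ends at 0.00612.

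Genes of DNA methylation and the methionine cycle had bodies near the genome mean, at 1.09 ± 0.0653, and ends at 0.0610 ± 0.0152. Of 28 tested bodies, 4 were above (Mtap, Tet3, Cbs and Mbd2) and 11 below expectation; over the list alone, 6 and 14. Of the engineered genes, the Dnmt1 body, on chromosome 9 from 20908206 to 20958888, had a relative density of 0.976 ± 0.308 (SD, n = 3), or 0.777 ± 0.235 of expectation (adjusted p = 0.04241, limma-moderated quasi-Poisson). Its CpG-richer end, with 23 CpG sites, stood at 1.43 ± 1.38, from 0, 33 and 59 tags, and this end is probably not the promoter. The Mat2a body, on chromosome 6 from 72433796 to 72438556, stood at 0.232 ± 0.401 with 31 CpG sites. All of its 20 tags were in double knock-in replicate 3. The Mat2a end, with 107 CpG sites, had no tag. No wild-type tag fell in the bodies or ends of either gene, and the tables do not show the engineered codons. The rule also took Mtr, methionine synthase, at 1.44 ± 0.229 and Mbd1, a methyl-CpG binding protein, at 1.38 ± 0.173.

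Imprinted genes were mixed. Their ends stood at 0.0676 ± 0.0163 with 15 of 25 members at 0 (percentile 49.55 of matched lists), and their bodies at 1.03 ± 0.0539. Among 16 tested bodies, 4 were above (Peg3, Rasgrf1, Slc38a4 and Igf2r) and 6 below expectation (7 over the list alone). Rasgrf1, a guanine nucleotide exchange factor, stood at 1.85 ± 0.265 and Snrpn, a splicing protein gene, at 0.176 ± 0.0246. Replication and chromatin genes had bodies at 0.882 ± 0.0465 and ends at 0.0374 ± 0.0240, with 3 of 26 bodies above (Trrap, Smarca4 and Pola1) and 12 below expectation. Trrap, a histone acetyltransferase subunit, stood at 1.80 ± 0.263 and Supt16, a histone chaperone, at 0.4445 ± 0.1004.

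Long neuronal genes and 3 large gene families were taken as lists of their own. Long neuronal genes had bodies at 0.849 ± 0.0262 with a member median of 0.597, at percentile 70.9 of matched lists and 53 after division by expectation. Of 25 tested bodies, 18 were below and 3 above expectation, among them Dab1 and Wwox, and 5 were at least 2-fold below. Il1rapl1, a synaptic receptor gene on the X chromosome, stood at 0.128 ± 0.0248, or 0.573 ± 0.101 of expectation, which includes the chromosome. Galntl6, a glycosyltransferase gene, stood at 0.671 ± 0.0494. Ends of the long neuronal genes stood at 0.0714 ± 0.0613. Bodies of the clustered protocadherins, cell adhesion receptors of neurons, stood at 0.271 ± 0.0573 (member median at percentile 0 of matched lists), with 39 of 57 below and none above expectation (40 over the list alone), and their ends at 0.0444 ± 0.0146, with 30 of 51 lower over the list alone. These genes share overlapping intervals, so their counts are not independent. Olfactory and vomeronasal receptor bodies stood at 0.375 ± 0.0342 (percentile 0), with 92 of 204 below and 6 above expectation (95 and 6 over the list alone), and their ends at 0.703 ± 0.0177, with 7 of 272 above (9 over the list alone). Zinc finger protein bodies stood at 1.07 ± 0.0252, and at 1.006 ± 0.0213 divided by expectation. Their member median was 0.644 (percentile 0 of matched random lists, which had a median of 0.788), and 115 of 391 were below and 30 above expectation. Their ends stood at 0.0664 ± 0.0154, with 2 of 233, Zfp354a and Zfp488, above expectation. Some receptor and zinc finger genes have near-identical copies, so the values of these lists are uncertain.

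Over all protein-coding genes, 2887 of 18109 bodies were above and 4193 below local expectation in the double knock-in (limma-moderated quasi-Poisson, Benjamini-Hochberg threshold 0.05). At least 2-fold differences were found for 460 and 2991 of them. Both counts fell whichever library was left out. Without replicate 1, 2 or 3, 2279, 2019 and 2396 bodies were above expectation. Below it were 2459, 2169 and 3193, and 1905, 1692 and 2408 at least 2-fold. Each such fit has fewer libraries to estimate the spread, so dependence on a single library is not shown. At gene ends 120 of 9658 passed, all of them higher except 3 (Tacr1, Gm42048 and Rtbdn, chosen after their values were seen), a test that recovered no lowered end in simulated data. With at least 100 expected tags, 308 ends were left, and 22 passed as higher and 123 as lower. At gene ends the calls fell to 26, 23 and 23 without replicate 1, 2 or 3. Without replicate 2 the bodies that differed at least 2-fold went from 3451 to 2070. The highest gene body was Sfi1, a centrosome gene on chromosome 11, at 10.4 ± 0.712 times the genome mean. It was followed by A230072I06Rik at 6.00 ± 0.202, Aida, a developmental signalling inhibitor, at 5.62 ± 0.522, Hjurp, the centromere histone chaperone, at 5.25 ± 0.739, and Cpa1, a pancreatic carboxypeptidase, at 5.19 ± 1.71. Without the 0.01% of sites with the most tags, Sfi1 stood at 3.58 and Aida at 1.22. A230072I06Rik lies on chromosome 8 and Cpa1 on chromosome 6, which carried more tags as a whole. Divided by expectation, which includes the chromosome, they stood at 2.967 ± 0.103 and 2.965 ± 0.9765. Among bodies with at least 50 CpG sites, 399 of 15910 had no tag, and those with the most sites were Gm16867, Gm4724, Ccl21b, Gm21451 and Rex2. Several of these have near-identical copies next to them.

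The rule also took the genes that follow. Among bodies, Tdrd9 stood at a relative density of 1.64 ± 0.335 and Smc1b at 0.407 ± 0.192 in the germline list. Among receptors Vmn2r1 stood at 0.812 ± 0.104 and Olfr524 at 2.99 ± 2.03, among zinc finger genes Zfp618 at 2.05 ± 0.126 and Zfp112 at 0.673 ± 0.209, and among protocadherins Pcdha1 at 0.253 ± 0.0471 and Pcdhb6 at 0.236 ± 0.382. Among gene ends, most without a wild-type tag, the rule took as largest in their lists Dlk1 (1.42 ± 0.353), Reep5 (0.572 ± 0.659), Nkx2-5 (0.612 ± 1.04), Lsamp (0.748 ± 1.27), Rfc1 (4.70 ± 4.28), Pcdhb22 (0.7001 ± 0.346), Olfr324 (4.63 ± 1.69) and Zfp488 (2.50 ± 1.22). As smallest it took Magel2 (0.0951 ± 0.165), Dppa3 (0.7525 ± 1.27), Hoxa9 (0.177 ± 0.306), Myh6 (0.224 ± 0.314), Shmt2 (0.0956 ± 0.166), Ep400 (0.0389 ± 0.0673), Pcdhb1 (0.133 ± 0.231), Olfr214 (1.99 ± 1.96) and Zfp637 (0.138 ± 0.239). Without the 0.01% of sites with the most tags, the Tuba3a end stood at 2.655.

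Compared as counted, the double knock-in exceeded the wild type across the genome, which the 1194-fold difference in total tags fixes in advance. With no scaling, 25198 of 25357 windows of 100 kb, 15050 of 17121 gene bodies and 30 of 5851 gene ends were higher in the double knock-in and none was lower (quasi-Poisson test moderated with limma). Compared as shares of each library, 0 windows, 0 gene bodies and 0 gene ends passed, with 114, 75 and 56 below an unadjusted p of 0.05. The wild-type depth leaves this test almost no power. The limma test on log2 values with voom weights, added after seeing the data, called 8250 windows (2415 higher), 7288 bodies and 0 ends, but it also called 40.2%, 45.0% and 57.6% of simulated unchanged features, so its calls carry no weight here. Among members of the lists, none passed the share test over all genes, and 1 gene body, Cdx2 of the Polycomb list, was lower adjusted over the list alone.

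Chromosomes 6 and 8 carried more tags than the other autosomes in the double knock-in. Divided by the tags expected from local CpG density and set to the median autosome, chromosome 6 stood at 1.515 ± 0.00986 and chromosome 8 at 1.60 ± 0.0111 (SD, n = 3), and the other 17 autosomes between 0.928 and 1.07. In the wild type, chromosomes 6 and 8 stood at 1.004 ± 0.108 and 1.14 ± 0.143, and the other autosomes between 0.730 and 1.22. As relative density, chromosome 6 was 1.478 ± 0.00776 in the double knock-in and 1.03 ± 0.123 in the wild type, and chromosome 8 was 1.591 ± 0.00548 and 1.19 ± 0.133 (exact permutation p = 0.10 each). The X chromosome had a relative density of 0.252 ± 0.00467 in the double knock-in and 0.316 ± 0.0156 in the wild type (exact permutation p = 0.10). It was low in both groups. Because the wild-type background was low there too, and the number of X copies in these cells was not measured, the low values do not show sparse labelling of the X.

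**Figure D5:**
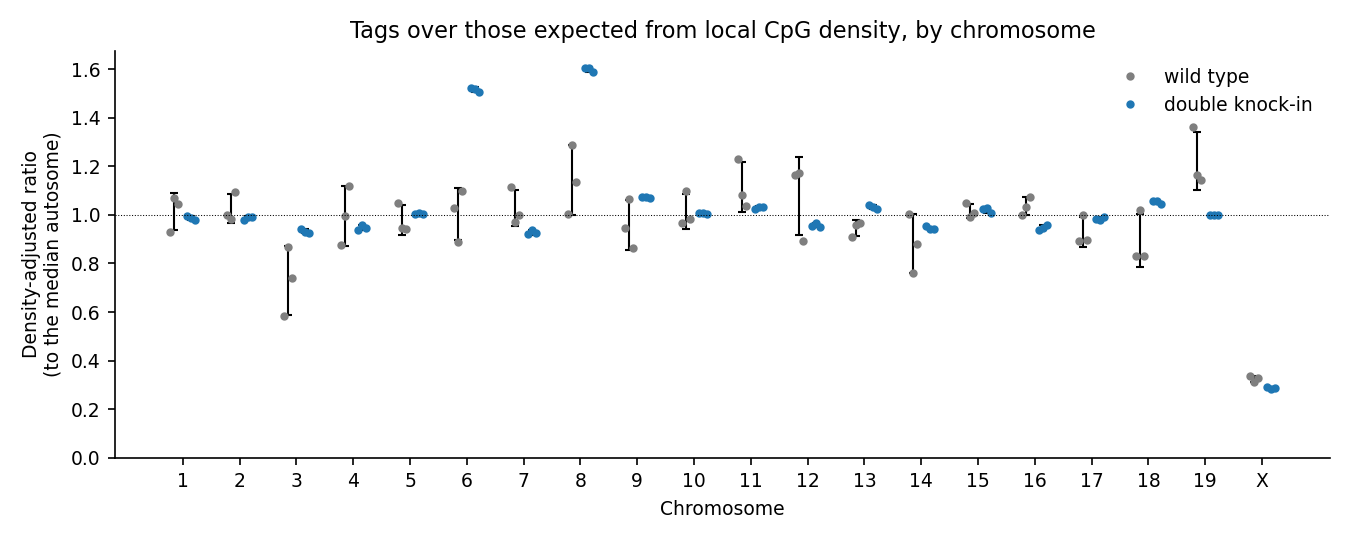
Tags over those expected from local CpG density, by chromosome, relative to the median autosome. Points are the 3 libraries of each group and error bars SD. In the double knock-in the other 17 autosomes lay between 0.928 and 1.07.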

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

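Tags at mitochondrial and Y chromosome sites lie outside the reference used for every comparison and exceeded the wild-type level as counted. The double knock-in libraries held 215.7 ± 28.9 tags on Y sites (SD, n = 3) against 4.33 ± 4.93 in the wild type, and 41.7 ± 26.3 tags on mitochondrial sites against 16 ± 7. As a share of the library the order was the reverse, with relative densities of 0.000439 against 0.0101 on the Y and 0.153 against 67.3 on mitochondrial DNA. The wild-type Y value rested mainly on replicate 2, as the libraries held 1, 10 and 2 tags. Double knock-in replicate 3 held 72 mitochondrial tags, where replicates 1 and 2 held 27 and 26. No group had enough libraries for a test of single outlying samples.

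All tests in this paragraph were chosen after the results were seen. The wild-type libraries held few tags with a distribution of their own. Carry-over of tags counted in the double knock-in libraries as the whole source is argued against by the sites themselves. Of the 9476 sites with a wild-type tag, 23.5% also had a double knock-in tag, where sites of equal density and chromosome gave 18.6%. Carry-over of labelled DNA before amplification is not addressed by this overlap. Pairs of double knock-in libraries themselves shared only 12.8% to 17.9% of their sites. Labelling of the same CpGs by the wild-type enzymes, or carry-over of labelled DNA, as the whole source would have left CpG-dense sites nearly empty. Their wild-type density was 0.450 ± 0.0311. Either of them as the source of part of the tags is not excluded, since a mixture would also give an intermediate density. Capture of DNA without any label stays open and may account for most wild-type tags, since mitochondrial CpGs, present in many copies per cell, held 67.3 times the nuclear density (42.1 to 82.0 per library), although on 3 to 6 sites per library.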

How the results depend on the processing

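The share comparisons rest on 14134 to 19087 wild-type tags per library, which is too few to decide single features. Scaling to the median of 5 Mb windows, the voom fit and all alternatives of the test against local expectation were chosen after seeing the data. The planned edgeR, DESeq2 and trimmed-mean alternatives were not run, and sites with over 40 CpGs within 100 bp held no tag in any library, so that class gave no ratio. Of 340 alternatives for single genes and list levels, 3 moved by more than the spread, but leaving out 1 of 3 libraries cannot move a mean that far. By fold, 39 of 255 such values changed over 1.5-fold, among them housekeeping ends (0.0028 to 0.00918), long neuronal ends (0.0363 to 0.093), Polycomb ends (0.0434 to 0.0796), the Dppa3 end (0.0196 to 1.13) and the Nkx2-5 end (0.00869 to 0.918). Total tags, covered sites, CpG-rich ends and CpG-dense sites kept their direction under each alternative run; the fold in covered sites was 451 as counted, 529 with at least 2 tags and 4.64 after thinning, which removes repeated tags mainly from the double knock-in.

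With CpGs counted within 100 bp, the ratio of double knock-in to wild type turned from 0.925 to 1.04 at sites with 1 to 5 CpGs nearby and from 1.03 to 0.306 at sites with 11 to 20, because the class then holds denser sequence. Leaving out each library in turn gave 0.9916 to 1.03 for sites outside annotated genes, turned without wild-type replicate 2, and 0.893 to 1.645 for CpG-poor ends, turned without wild-type replicate 2 (0.893) or 3 (0.971). In 10 kb windows the mean Pearson's r fell to 0.607 within the double knock-in and 0.00425 within the wild type.

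Against 0 calls in the share test, no scaling gave 25198 windows, 15050 gene bodies and 30 gene ends, and the voom fit 8250, 7288 and 0; counting sites as 1 or 0 gave 2 windows and 5 ends, and 1 Mb windows gave 1. Leaving out each library gave 0 to 1 windows, and 0 to 1 lists at gene bodies, the 0 without wild-type replicate 2. The replicate numbers did not pair the libraries: the Spearman correlations of same-numbered deviations were -0.015, -0.0126 and 0.0189, and not every sample correlated best with its own number. With the replicate block, 367 windows, 308 gene bodies and 0 gene ends were called, all lower, and 0 lists at gene bodies. That fit gives a p-value only to features with a wild-type tag, 7221 of 25357 windows and 3249 of 17121 gene bodies. The cause of these changes was not tested. Against local expectation, leaving out each double knock-in library gave 2070 to 2844 gene bodies of at least 2-fold difference in place of 3451, and 23 to 26 gene ends in place of 120, with fewer libraries to estimate the spread. With at least 100 expected tags, 308 ends could be tested, and 21 were at least 2-fold higher and 123 lower, where 3 of the 120 were lower before.

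With 6 samples there are 10 splits into 3 and 3, too few for a share under 0.05. The real split called 0 windows, 0 gene bodies and 0 gene ends, and the highest of the others 4324, 3953 and 1381, and against a real count of 0 all 10 splits are as large by construction. For the lists the real count was 0 at ends, with 0 as the highest other and 10 of 10 splits as large, and 1 at bodies, with 1 as the highest other and 7 of 10 splits as large.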

Other observations

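Other gene families differed in the density of their bodies in the double knock-in, in a test chosen after the data were seen. Families were genes with the same letters before the first digit of the symbol, and the median of observed over expected tags was set against 10000 random lists matched on CpG sites per kb; 8 of 137 families were higher and 15 lower (Benjamini-Hochberg adjusted permutation p under the threshold). Keratins (Krt, 53 genes) had a median of 1.60 against 0.920 in random lists and beta-defensins (Defb, 18 genes) 1.58 against 0.863, both with adjusted p = 0.00228, where 0.0002 is the smallest unadjusted p that the permutations can give. ATPases and related genes (Atp, 81 genes, 1.10 against 0.875, adjusted p = 0.013), Galnt genes (17 genes, 1.40, adjusted p = 0.00806), Kcnj channels (15 genes, 1.34, adjusted p = 0.0324), collagens (Col, 44 genes, 1.25, adjusted p = 0.00421), kallikreins (Klk, 25 genes, 1.24, adjusted p = 0.00731) and solute carriers (Slc, 371 genes, 1.04, adjusted p = 0.00228) were higher as well. Neighbouring members of such clusters are not independent, so these p-values are too small.

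Several families of ribosomal proteins and translation factors lay low. The trim of 1000 bp leaves part of the depletion around CpG-rich ends in gene bodies, and the matching does not account for it. Ribosomal protein genes (Rpl, 37 genes) had a median of 0 with 27 members at 0, and Rps genes (31 genes) 0.0547, against 0.776 and 0.845 in random lists (adjusted p = 0.00228 each). Mitochondrial ribosomal proteins (Mrpl, 42 genes, 0.569, adjusted p = 0.00587), translation initiation factors (Eif, 52 genes, 0.608, adjusted p = 0.0107) and elongation factors (Eef, 15 genes, 0.469, adjusted p = 0.0393) were lower too, as were Mrps (0.479, adjusted p = 0.00806), Rbm (0.622, adjusted p = 0.0205) and Cox genes (0.489, adjusted p = 0.0300). Receptor and zinc finger families (Olfr 0.385, Vmn 0.218, Zfp 0.672) were lower with adjusted p = 0.00228 each. Clusters of related genes, some of them near-identical, were also at 0 in median. They were major urinary proteins (Mup, 17 of 20 genes at 0), Rhox genes (18 of 33), Pramel genes (21 of 39) and Prl genes (15 of 25). In such clusters unplaced reads cannot be separated from missing label. Ribosomal protein genes have many processed copies, so part of their reads may share this limit.

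The tests in this and the next paragraph were chosen after the results were seen. Chromosomes 6 and 8 carried more tags in the double knock-in. Local CpG density does not account for this, since the lower of both adjusted ratios was 1.515 and the highest other autosome 1.07. Few heavily tagged sites do not either, since with each site counted as 1 or 0 the lower ratio was 1.43 against 1.07. A candidate explanation is a larger copy number of both chromosomes in the double knock-in cells: 96.4% of their 28 windows of 10 Mb lay above the median window of the other autosomes, with medians of 1.52 and 1.53 against 0.957. It remains a hypothesis, because genotype and cell line cannot be separated and no unlabelled input shows the copies themselves.

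The highest gene bodies may hold more copies in these cells than in the reference. For Sfi1, the wild-type libraries had 5 covered sites, 16.5 times those expected (95% Poisson interval 5.36 to 38.5), and all 3 held tags there. Carry-over of part of the wild-type tags is not excluded and would reach a gene with this many tags, so the explanation stays open. By tags, the double knock-in density of Sfi1 was 10.4, and 3.58 without the 0.01% of sites with the most tags. For the other 4 genes together, 1 covered site gave 4.15 times the expected number (0.105 to 23.1), too few to decide. Aida lost most of its excess without the sites with the most tags. Divided by expectation, which includes the chromosome, A230072I06Rik stood at 2.967 and Cpa1 at 2.965.

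Of the 20 sites with the most tags, 13 lay on chromosome 2 between 98662601 and 98667325 (mm10). A region around them held 0.0440% to 0.105% of the tags of the wild-type libraries and 0.0456% to 0.0535% of those of the double knock-in, with 8 to 20 tags per wild-type library, so a special role of the label there is not shown. The ratio of X to autosomal 100 kb windows in the double knock-in was 0.0917, 0.2445, 0.264, 0.261 and 0.263 at the 10th, 25th, 50th, 75th and 90th percentile. The number of X copies enters these ratios and was not measured.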
